A study of Mus musculus with 2 samples.

How the data were processed

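Skin of female SKH-1 mice was profiled on Visium slides, which capture transcripts at barcoded spots laid over a tissue section. Per the labels' protocols, probe-based libraries of the kit for fixed tissue were made from fresh-frozen sections. The deposited matrices hold raw UMI counts per gene and spot, which the authors made with Space Ranger 2.0.0 against mm10, per the submitters' processing notes, which also name Seurat 4.1.0; only the raw counts were used here. Each matrix had 19465 genes, 11 of them with a repeated symbol, and listed only spots over tissue. The 2 capture areas each carried 2 sections, which the labels name as upper and lower. Sections were split at the gap between tissue pieces, and upper was read as the smaller image row before the data were examined. The spot grid runs opposite to the image row on both areas, so reading the grid instead exchanges the groups. That alternative was run over the whole section for counts of genes, list medians, named genes and the position between control and UVR, but not within regions. Gene coordinates come from a table of GRCm38.p6 genes joined by symbol, which matched 19080 genes; mm10 is the same assembly.

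Spots with at least 200 UMIs were kept: 72.9% of 465 control spots, 68.9% of 939 UVR spots, 69.1% of 787 retinol-treated spots and 65.4% of 984 HPR-treated spots. The kept spots had median depths of 527, 1641, 982 and 653 UMIs, in that order. Counts were summed over the kept spots of a section or region and divided by its total to give CPM. Groups were compared as ratios of CPM without a pseudocount, for genes with at least 100 UMIs over both sections. Each ratio has an exact (Clopper-Pearson) 95% interval from the binomial split of a gene's UMIs between both sections. A group with 0 UMIs was set to 3 counts, which makes the ratio a bound. With 1 section per group, variation between animals could not be measured; intervals and limits cover counting error only, no p-value was computed, and spots were not used as replicates. The 4 comparisons were UVR over control, each treatment over UVR, and HPR over retinol. A fold of 2 was the size rule for single genes.

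Spots of all sections were clustered together with scanpy 1.11.5: counts were scaled to 10000 per spot and logged, 2000 variable genes were chosen without the genes of the outcome lists, and Leiden clustering at resolution 0.5 ran on 20 principal components with 15 neighbours. The planned naming rule asked for at least 3 genes of 1 marker list among a cluster's top 20 genes. It named only region 0 (skeletal muscle) and region 3 (adipocyte), so a different rule was adopted after the clusters were seen. Under it, a region took the layer whose muscle, sebaceous or fibroblast markers had the highest median log2 fold, if that was at least 2, and was otherwise called outer. The layers are the outer pair (regions 1 and 2), the middle region 3, the muscle pair (regions 0 and 4) and region 5, rich in *Scd1*. A spot covers several cells, so no cell types were called. Keratinocyte transcripts also reached spots of the middle region.

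Before the data were examined, 16 lists of outcome genes and 13 lists of cell-type markers were written. A list's value is the median log2 ratio of members with at least 20 UMIs over both sections, with a percentile among 10000 random lists matched in 20 abundance bins and a counting interval from 200 Poisson draws. Percentiles describe where a list lies and are not tests. The rule for named genes was also set then. It takes, in each comparison, the 6 highest and 6 lowest whole-section ratios with at least 200 UMIs and at least 2-fold, in the same direction between each left or right image side of 1 section and each of the other, and the 5 highest and lowest within the outer and the middle region with at least 100 UMIs. It adds 2 members at each end of every outcome list and a fixed set of skin genes. Some genes picked by the rule are left out of the text because they were withheld for evaluation. *H2-Ab1*, *Igkc*, *Jup* and the myosin genes in the closing part were chosen after their values were seen.

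Scripts ran on Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9. They were tested on simulated counts drawn from the sections' own means and totals with 200 genes changed. For UVR over control (2292 genes) all 4-fold changes and 87.2% of 2.5-fold changes were recovered, and 11 unchanged genes passed 2-fold. For retinol over UVR (2874 genes) the shares were 100% and 96.0%, with 2 such genes. For HPR over UVR (2804 genes) they were 100% and 91.0%, with none, and for HPR over retinol (2155 genes) 100% and 91.9%, with 1. Intervals covered the true ratio for 95.5%, 95.8%, 95.5% and 96.3% of genes. Of 40 unchanged lists per comparison, 1, 2, 0 and 3 fell outside the middle 95% of random lists.

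Alternatives covered scaling, spot and gene filters, a pseudocount of 1 CPM, depth thinning, image sides, tissue composition, the reading of upper and lower, and the clustering. Those on single regions, on image sides or equal total UMIs of the outer regions, and without both muscle regions were chosen after seeing the data, as was the position under the exchanged groups. No histology images were used here.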

Results

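Spatial transcriptomes were measured in skin sections of female SKH-1 mice, a hairless strain. The 4 groups were untreated control skin, skin exposed to ultraviolet radiation (UVR), UVR-exposed skin treated with 0.1% retinol, and UVR-exposed skin treated with 0.03% 9-cis HPR, a retinoid. Each group had 1 section, so there were no replicates; the values below carry no test, and their intervals cover counting error only. Control and UVR skin lay on 1 capture area, and both treated skins lay on another. After spots with fewer than 200 unique molecular identifiers (UMIs) were left out, control skin kept 339 spots with 326095 UMIs and UVR skin 647 spots with 2558616 UMIs. Retinol-treated skin kept 544 spots with 1414976 UMIs, and HPR-treated skin 644 spots with 1249928 UMIs. A gene with no UMI could have reached 9.20 CPM (counts scaled by total UMIs) in control skin, 1.17 CPM in UVR skin, 2.12 CPM in retinol-treated skin and 2.40 CPM in HPR-treated skin. Groups were assigned by upper and lower position in the image. The files do not settle whether the labels meant the image or the spot grid, and the grid would exchange the 2 groups on each area. That turns every direction within an area and also changes the comparisons of treated with UVR skin.

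Clustering of spots by expression gave 6 regions in the tissue. An outer pair of regions, read as epidermal, comprised region 1, with *Col7a1*, *Ticrr*, *Cenpm* and histone genes on top, and region 2, with cornification genes such as *Lor*, *Crct1*, *Cdsn* and *Hrnr*. Neither had a keratinocyte marker of the fixed list among its top 20 genes. A middle region carried *Trem2*, *Mpeg1*, *Cd36*, *Cfd* and *Bgn*, and macrophage and dendritic markers (median log2 fold 3.48) and fibroblast markers (3.32) were high there. A pair of muscle regions carried *Myh4*, *Pvalb* and *Myh2*, and a small region carried the lipid genes *Scd1* and *Fa2h*. The outer regions held 25.7% of control spots (exact binomial 95% interval 21.1% to 30.7%), 42.3% of UVR spots (38.5% to 46.3%), 36.9% of retinol-treated spots and 34.5% of HPR-treated spots. They held 51.8% of all control UMIs, against 83.0% in UVR skin, 83.3% in retinol-treated skin and 80.3% in HPR-treated skin. The middle region supplied 29.6% of control UMIs, 4.51% of UVR UMIs, 7.39% of retinol-treated UMIs and 10.2% of HPR-treated UMIs. Whole-section ratios therefore mix tissue layers in different shares, and values within a region are given for some genes only.

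**Figure D1:**
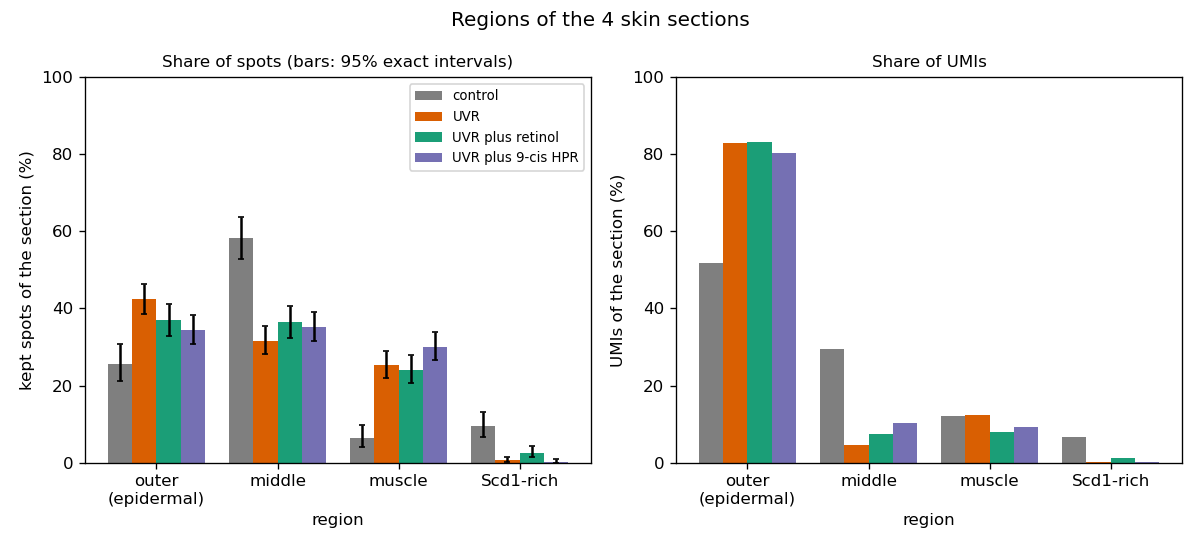
Share of kept spots (left, %) and of UMIs (right, %) in the outer, middle, muscle and *Scd1*-rich regions of the 4 sections, with exact 95% intervals for spots. The outer regions held 51.8% of UMIs in control skin and 80.3% to 83.3% in the other sections.

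UVR against control skin addressed how irradiation altered the skin. The epidermis of UVR skin carried far more wound-type keratin and small proline-rich transcripts than control epidermis. In the outer regions, *Krt16*, a keratin of stressed epidermis, was 35.3-fold higher (95% interval 26.1 to 49.0), *Krt6b* 38.9-fold higher (31.0 to 49.3), *Sprr1a* 42.9-fold higher (22.6 to 93.8) and *Sprr1b* 28.9-fold higher (24.8 to 33.9). The list of stress keratin and hyperproliferation genes had a median log2 ratio of 2.87 there (2.36 to 3.43), and all 14 measured members were at least 1.5-fold higher. Cell-division genes were also higher, with a list median of 1.39 (0.76 to 1.60) over 15 genes that included *Mcm2*, *Mcm4* and *Mcm5*. Both lists lay at percentile 100 among 10000 random lists of matched abundance. Control skin had 12 spots in region 1 and 75 in region 2, against 176 and 98 in UVR skin. Within region 1 alone the division list had a median of 0.29 (-0.55 to 0.47) and within region 2 alone 0.48 (-0.04 to 0.80), both smaller than over the pair. The stress keratin medians there were 2.37 (1.86 to 2.89) and 3.05 (2.49 to 3.48). When the outcome genes were allowed to define the clusters, only 9 control spots, with 10494 UMIs, stayed in the outer regions. Another 150 control spots fell in a region with *Krt77*, *Krt10* and *Scd1* on top, which the layer rule called *Scd1*-rich. On the 9 spots left, the medians turned to -0.66 for stress keratins and -2.01 for division genes. These medians thus do not compare the same control spots.

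*Krt16* (ENSMUSG00000053797, chromosome 11, 100246091 to 100248902 of GRCm38) had 18774 UMIs in UVR skin and 91 in control skin, 26.3-fold higher over the whole section (21.4 to 32.7). *Krt6b* (ENSMUSG00000023041, chromosome 15, 101676023 to 101680293) was 26.1-fold higher, and *Sprr1b* (ENSMUSG00000048455, chromosome 3, 92436808 to 92438817) was 23.6-fold higher. *Tcf23*, a helix-loop-helix factor gene, had 584 UMIs against 2 in control skin, a ratio of 37.2 (10.3 to 308). *Sprr2j-ps*, a pseudogene of the small proline-rich cluster, had 233 UMIs against 1, and the water-channel gene *Aqp5* had 341 against 3, a ratio of 14.5 (4.92 to 70.6). The basal keratin *Krt14* was 6.07-fold higher (5.66 to 6.51) and its partner *Krt5* 2.17-fold higher (2.11 to 2.23). The glycerol channel *Aqp3* was 10.1-fold higher (8.48 to 12.2). The retinoic acid-binding gene *Crabp2* was 2.87-fold higher (2.48 to 3.33), and the growth-factor gene *Areg* had 254 UMIs against 6, a ratio of 5.40 (2.44 to 14.8). *Cdkn1a*, a p53 target, was 1.31-fold higher (1.24 to 1.38), *Phlda3* 3.01-fold higher (2.31 to 4) and the metallothionein *Mt1* 2.39-fold higher (2.20 to 2.59). The p53 list as a whole had a median log2 ratio of only 0.05 over the section, so *Cdkn1a* and *Phlda3* do not stand for it.

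Some differentiation and antigen-presentation genes were lower in UVR skin. *Krt77*, a keratin of suprabasal epidermis (ENSMUSG00000067594, chromosome 15, 101858731 to 101869706), had 6 UMIs in UVR skin against 296 in control skin, 387-fold lower (176 to 1060). *Krt10* was 7.45-fold lower (6.91 to 8.02), *Lor*, the main cornified-envelope protein gene, 3.53-fold lower (3.47 to 3.60) and filaggrin (*Flg*) 2.98-fold lower (2.59 to 3.42). Within the epidermal regions *Krt10* was 10.5-fold lower, *Lor* 4.92-fold lower and *Flg* 4.11-fold lower. The whole spinous and cornified envelope list had a median of -0.34 (-0.54 to 0.05) over the section, and in the outer pair -1.20 in region 1 and 0.26 in region 2. *Cd74*, the invariant chain of antigen-presenting cells, was 11.3-fold lower over the section (9.25 to 13.8) and 13.7-fold lower in the outer regions (9.95 to 18.9). The macrophage and dendritic marker list had an outer-region median of -2.38 (-2.95 to -1.97), with all 5 measured genes lower. The inflammatory list, at -0.28 (-0.84 to 0.16), and the interferon list, at -0.72 (-1.30 to 0.14), were within counting error of no difference over the section. *Igha* was 2.77-fold lower over the section and 2.22-fold lower in the outer regions, but 2.78-fold higher in the middle region (2.31 to 3.36). *Paqr7* was 29.2-fold lower, the lipid hydroxylase *Fa2h* 12.1-fold lower, the tenascin gene *Tnxb* 11.5-fold lower and *Ccdc3* 11.4-fold lower over the whole section. *Paqr7* and *Fa2h* were top genes of the *Scd1*-rich region, which held 32 control and 4 UVR spots; in the outer regions they were 9.12-fold and 4.24-fold lower. Hair follicle markers had a whole-section median of -2.02 and sebaceous gland markers -1.16; the latter ended at 0.0126 with equal total UMIs per section.

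Collagen and other matrix transcripts were lower over the whole UVR section but not within its middle region. *Col1a1* was 5.51-fold lower (4.22 to 7.17) and *Col3a1* 3.87-fold lower (3.12 to 4.77) over the section. In the middle region *Col1a1* was 1.20-fold lower (0.87 to 1.64) and *Col3a1* was 1.22-fold higher (0.95 to 1.57). The list of collagens and dermal matrix genes had a median of -1.27 (-1.60 to -0.93) over the section, 0.30 (0.05 to 0.52) in the middle region and 0.11 (-0.40 to 0.47) in the outer regions. With the outer pair, the middle region and the muscle pair given the same weights in both sections, the whole-section median turned to 0.25. The *Scd1*-rich region, with 4 UVR spots, was left out of this weighting, and regions 1 and 2 stayed pooled. Matrix protease genes had a whole-section median of -1.92 and a middle-region median of -0.23 (-0.66 to 0.05). *Mmp13*, *Timp1*, *Il1b*, *Cxcl1*, *Ivl* and *Mki67* had too few UMIs for a difference to be detectable at this depth.

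Of 2510 genes compared over the section, 312 were at least 2-fold higher in UVR skin and 191 at least 2-fold lower. The balance turned to 760 higher and 1026 lower of 5898 genes with a minimum of 20 UMIs. With no minimum and a pseudocount of 1 CPM it turned to 2167 and 3364 of 13026 genes. Within the outer regions the counts were 392 and 120 of 2014 genes. Control skin had the fewest UMIs, so its low-abundance genes rested on few counts, and counting error alone can carry such genes past 2-fold.

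**Figure D2:**
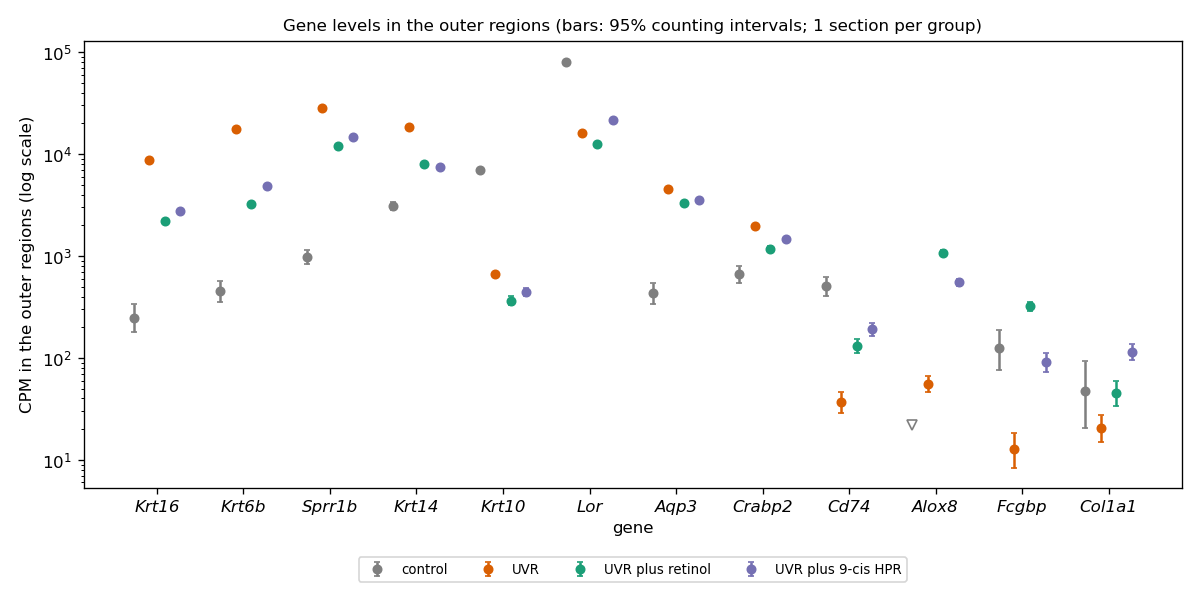
CPM (log scale) of 12 genes in the outer regions of the 4 sections, with 95% counting intervals; the open triangle is the upper limit for a gene with no UMI. *Krt16*, *Krt6b* and *Sprr1b* were highest in UVR skin, intermediate in both treated skins and lowest in control skin, whereas *Krt10* was highest in control skin.

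Retinol-treated against UVR skin addressed what topical retinol changed in irradiated skin. The stress keratins and dividing-cell genes were lower in retinol-treated epidermis. Within the outer regions *Krt6b* was 5.36-fold lower (5.19 to 5.54), *Krt16* 3.96-fold lower (3.80 to 4.13) and *Krt14* 2.30-fold lower (2.24 to 2.35). The stress keratin list had a median of -0.81 (-1.26 to -0.68) and the proliferation list -1.45 (-1.75 to -1.33), with all 16 measured division genes at least 1.5-fold lower. *Mcm2* was 2.76-fold lower (2.42 to 3.14) and the cyclin gene *Ccnd1* 8.69-fold lower (5.89 to 13.3). These sections lay on different capture areas, so area and treatment cannot be told apart. With groups read by the spot grid, the whole-section stress keratin median turned from -0.82 to 2.07, the *Krt16* log2 ratio from -1.95 to 3.05 and the proliferation median from -1.31 to -0.0915.

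Among the highest genes over the whole section were *Fcgbp*, a mucus-type binding protein gene, 25.8-fold higher (17.7 to 39.0; ENSMUSG00000047730, chromosome 7, 28071236 to 28120864), and *Alox8*, a skin lipoxygenase gene, 19.3-fold higher (16.0 to 23.4; ENSMUSG00000020891, chromosome 11, 69183885 to 69197843). *Sult5a1* was 10.8-fold higher, *Alox12e* 7.37-fold higher and *Wnt3* 6.73-fold higher, and each kept an outer-region ratio above 6.5. The lowest were *Cyp2s1*, an epithelial cytochrome P450 gene (ENSMUSG00000040703, chromosome 7, 25802469 to 25816525), 10.0-fold lower (6.59 to 16.0), *Krt78* 9.04-fold lower, *Alox12* 8.33-fold lower, *Ccnd1* 7.57-fold lower, *Tppp3* 6.66-fold lower and the oxidase gene *Duox1* 5.65-fold lower. Reading by the spot grid turned the log2 ratios of *Fcgbp* from 4.69 to -0.37, *Ccnd1* from -2.92 to 0.17 and *Duox1* from -2.5 to 0.38. It shrank *Wnt3* from 2.75 to 0.31 and *Cyp2s1* from -3.33 to -0.62, and *Alox8* went from 4.27 to 6.23. Growth-factor genes moved apart: *Hbegf* was 3.25-fold higher (2.54 to 4.17) and *Areg* 1.83-fold higher (1.53 to 2.18), but *Ereg* was 2.53-fold lower (1.92 to 3.38). *Crabp2* was 1.64-fold lower (1.54 to 1.74).

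Differentiation genes went both ways in retinol-treated skin, with more of them lower. The spinous and cornified envelope list had an outer-region median of -0.74 (-0.87 to -0.53). *Cdsn*, which glues corneocytes, was 5.13-fold lower (4.71 to 5.60), *Krt10* 1.79-fold lower (1.61 to 2.00) and *Lor* 1.28-fold lower (1.25 to 1.30). *Krt77*, on 16 UMIs against 4 in the outer regions, was 7.21-fold higher there (2.33 to 29.6) and *Krt1* 1.17-fold higher (1.03 to 1.33). *Mt1* was 2.36-fold lower (2.26 to 2.46), and the antioxidant list had an outer-region median of -0.64 (-0.90 to -0.38). The p53 list had a whole-section median of -0.40 (-0.62 to -0.23), although *Cdkn2b* was 2.61-fold higher and *Bbc3* 2.09-fold higher. Macrophage and dendritic markers were higher in the outer regions, with a median of 1.47 (1.08 to 1.89), and the chemokine gene *Ccl8* was 4.37-fold higher (2.84 to 6.88). Collagens had a whole-section median of 0.40 (0.21 to 0.70) and a middle-region median of -0.20 (-0.47 to 0.06); the left side of the image gave 0.0033 for the section. *Col1a1* was 2.17-fold higher in the outer regions (1.43 to 3.31) and 2.03-fold lower in the middle region (1.36 to 3.08). Of 2932 genes compared, 124 were at least 2-fold higher and 267 at least 2-fold lower. The excess of lower genes was lost with equal total UMIs (61 and 59 of 944 genes) and with the spot-grid reading (119 and 122 of 1641). It shrank to 51 and 71 of 1117 genes from 500 UMIs. Equal totals also left out less abundant genes, so depth and the choice of genes are not separated there.

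HPR-treated against UVR skin addressed the same question for 9-cis HPR. The stress keratin and division genes were again lower in the epidermis. Collagen transcripts were higher over the section and in the outer regions, but their middle-region list median was within counting error of no difference. Within the outer regions *Krt16* was 3.16-fold lower (3.04 to 3.29), *Krt6b* 3.61-fold lower (3.50 to 3.72) and *Krt14* 2.44-fold lower (2.38 to 2.5). The stress keratin median was -0.95 (-1.12 to -0.71) and the proliferation median -1.60 (-1.74 to -1.34). Unlike in retinol-treated skin, *Lor* and *Flg* were higher than in UVR skin over the section, 1.31-fold (1.28 to 1.33) and 1.47-fold (1.31 to 1.64), and *Hrnr*, a filaggrin relative, was 3.23-fold higher (2.37 to 4.44). The spinous and cornified envelope list as a whole was lower, at -0.41 (-0.58 to -0.28), as was *Krt10*, 1.48-fold (1.33 to 1.64). Here too, capture area and treatment cannot be told apart. With groups read by the spot grid, the whole-section stress keratin median turned from -1 to 1.79 and the proliferation median from -1.38 to 0.17. Collagens turned from 1.03 to -0.78, and the log2 ratios of *Lor* and *Flg* from 0.38 and 0.55 to -2.17 and -1.93.

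*Col3a1* was 3.98-fold higher over the section (3.43 to 4.63) and *Col1a1* 3.21-fold higher (2.59 to 3.99). In the outer regions the ratios were 5.73 (4.47 to 7.39) and 5.58 (3.91 to 8.08), and in the middle region *Col3a1* was 1.36-fold higher (1.11 to 1.68) and *Col1a1* 1.11-fold lower (0.80 to 1.52). The collagen list had a median of 1.03 (0.88 to 1.32) over the section, 1.02 (0.76 to 1.36) in the outer regions and 0.10 (-0.31 to 0.34) in the middle region. That region supplied 10.2% of HPR-treated UMIs against 4.51% of UVR UMIs. With the outer, middle and muscle layers weighted alike, and the *Scd1*-rich region left out, the whole-section median was 0.25. *Alox8* was 9.68-fold higher over the section (7.95 to 11.9), *Sult5a1* 5.63-fold, *Wnt3* 4.80-fold, the potassium-channel gene *Kcnc4* 4.68-fold, *Srcin1* 4.58-fold and *Was* 4.39-fold higher. *Cyp2s1* was 10.2-fold lower (6.51 to 16.8), *Sprr2j-ps* 7.59-fold lower and *Krt78* 6.10-fold lower. The spot-grid reading turned the log2 ratios of *Sprr2j-ps* from -2.92 to 4.81, *Srcin1* from 2.20 to -0.47 and *Was* from 2.14 to -0.045. *Alox8*, *Sult5a1*, *Wnt3*, *Kcnc4*, *Cyp2s1* and *Krt78* kept their direction. The muscle genes *Myh4*, *Pvalb* and *Mlf1* were 7.58-fold, 6.38-fold and 5.40-fold lower, and region 0, which they led, held 130 UVR spots and 0 HPR-treated spots.

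The interferon list had a median of 0.99 (0.41 to 1.25) over the section, with *Irf9* 2.59-fold higher and *Psmb8* 2.39-fold higher; counting each spot equally turned the median to -0.0630. Macrophage and dendritic markers had an outer-region median of 1.5 (1.16 to 1.93). *Areg* was 1.68-fold lower (1.29 to 2.20) and *Fa2h* 3.33-fold lower (2.14 to 5.41) over the section, opposite to their directions in retinol-treated skin. *Mt1* was 2.47-fold lower (2.36 to 2.58) and the p53 list had a whole-section median of -0.69 (-0.89 to -0.45). Of 2813 genes compared, 96 were at least 2-fold higher and 259 at least 2-fold lower. Median-of-ratios scaling moved the median of all genes by 0.11 on the log2 scale and gave 131 higher and 203 lower genes, and the spot-grid reading turned the balance to 214 higher and 145 lower.

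Both treatments were set against the same UVR section, so their ratios share its counts. Across 2785 genes with at least 100 UMIs in both comparisons the log2 ratios had a correlation of 0.81 (across genes, which are not independent replicates), against 0.34 in simulated sections that differed by counting error alone. *Alox8*, *Sult5a1* and *Wnt3* were among 60 genes at least 2-fold higher in both comparisons, and *Cyp2s1* and *Krt78* among 161 at least 2-fold lower in both. Of the 312 genes higher in UVR than control skin, retinol-treated skin was nearer to control for 102 and HPR-treated skin for 128. Of the 191 lower genes, the counts were 39 and 51. With groups read by the spot grid, the counts were 140 and 152 of 191 higher genes and 184 and 210 of 312 lower genes, so they rest on the reading of the labels. With genes chosen on 1 random part of the UVR spots, the other part was nearer to control for 0.743% of the higher genes. Both parts came from the same section, so this share holds no variation between mice, sections or capture areas. It therefore cannot show whether the counts above exceed what another UVR section would give. *Krt16* in the outer regions stood at 249 CPM in control, 8767 CPM in UVR, 2212 CPM in retinol-treated and 2771 CPM in HPR-treated skin.

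**Figure D3:**
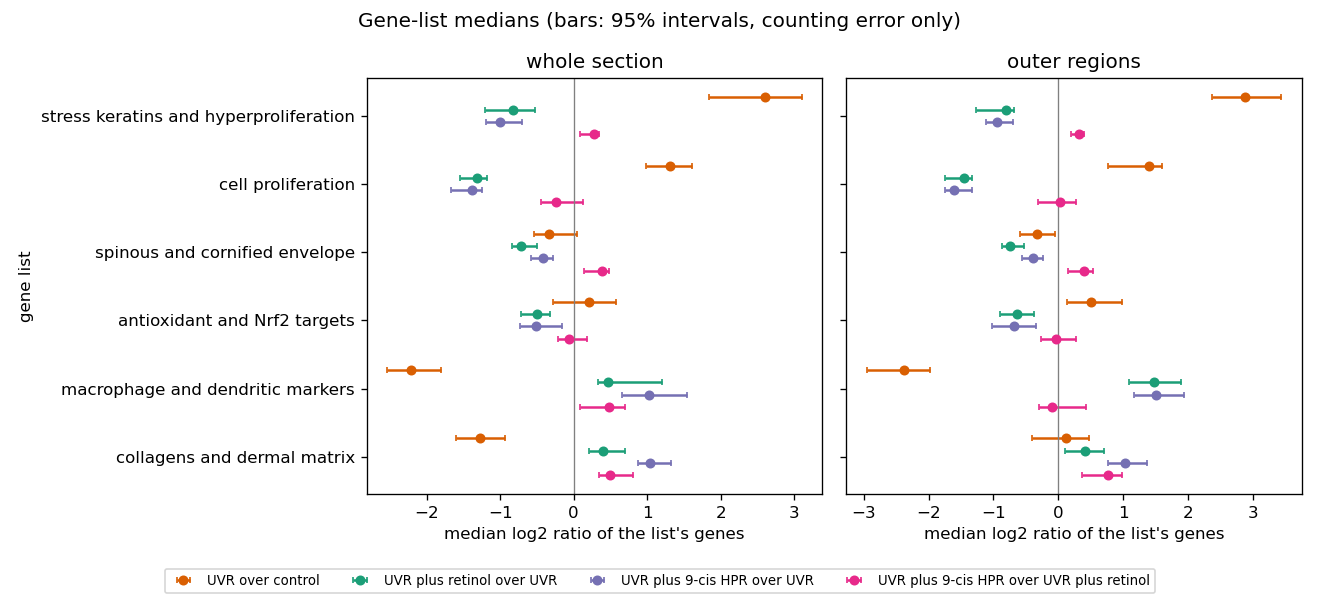
Median log2 ratio of 6 gene lists in the 4 comparisons, over the whole section (left) and in the outer regions (right), with 95% intervals for counting error only. The stress keratin list stood at 2.87 for UVR over control in the outer regions and at -0.81 and -0.95 for the 2 treatments over UVR.

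HPR-treated against retinol-treated skin compared the retinoids on the same capture area, at different doses. Few genes passed the 2-fold rule: of 2231 genes compared, 19 were at least 2-fold higher and 41 at least 2-fold lower in HPR-treated skin. *Col1a1* was 2.43-fold higher over the section (1.91 to 3.10) and 1.84-fold higher in the middle region (1.23 to 2.79), and *Col3a1* was 1.67-fold higher over the section (1.46 to 1.92). The cornification genes *Lor*, *Flg* and *Hrnr* were 1.67-fold (1.63 to 1.70), 1.88-fold (1.63 to 2.16) and 2.52-fold (1.78 to 3.60) higher. *Krt16* was 1.22-fold higher (1.15 to 1.28). Dose, compound and section cannot be separated with 1 section each.

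The other genes highest over the HPR section were *Pkd2*, 2.43-fold (1.90 to 3.13), the myosin light chain gene *Myl12a*, 2.29-fold, and *Igha*, the IgA heavy chain gene, 2.28-fold (1.95 to 2.68) and 2.81-fold in the middle region (2.26 to 3.51). Among the genes lowest in HPR-treated skin were *Fcgbp*, 3.52-fold (2.83 to 4.40), *Alox12e*, 3.50-fold (3.13 to 3.92), *Myh4*, 3.19-fold, *Areg*, 3.07-fold (2.36 to 4.03), and *Hbegf*, 2.87-fold (2.12 to 3.93). Without the muscle regions the *Myh4* log2 ratio turned to 0.25. *Fa2h* was 6.11-fold lower (3.93 to 9.91) over the section and 2.01-fold lower in the outer regions (0.96 to 4.52). *Tgfb1* was 1.91-fold lower (1.52 to 2.41).

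The collagen list had a median of 0.49 (0.35 to 0.81) over the section, 0.76 in the outer regions and 0.34 (0.16 to 0.63) in the middle region, but the right side of the image gave -0.0391 for the section and -0.0509 for the outer regions. The spinous and cornified envelope list had an outer-region median of 0.40 (0.14 to 0.53) and the stress keratin list 0.32 (0.19 to 0.39). The proliferation list had a median of 0.02 (-0.32 to 0.27), within counting error of no difference. Scaling evened the balance of calls: median-of-ratios factors gave 30 higher and 29 lower genes, and totals without the 50 most abundant genes gave 32 and 27. Lower genes stayed in excess with each spot counted equally (40 and 89), with equal total UMIs (1 and 19 of 920) and from 500 UMIs (1 and 10 of 762).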

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

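The tests of collagens and stress keratins in this part, and the bounds set for the simulated covariance, were chosen after the results were seen. The covariance itself was planned, and the outcome of the comparison of the capture areas in the muscle regions was unknown when its bounds were written. *Areg* and *Fa2h* stood out because the 2 treated skins lay on opposite sides of UVR skin by at least 1.5-fold, among genes compared in both. *Areg*, which encodes a ligand of the epidermal growth factor receptor, had a log2 ratio of HPR over retinol of -1.62; it stood at 182 CPM in retinol-treated, 59.2 CPM in HPR-treated and 99.3 CPM in UVR skin. *Fa2h*, needed for hydroxylated skin lipids, had a log2 ratio of -2.61, with 112, 18.4 and 61.4 CPM. In the outer regions *Areg* kept its opposite directions, whereas *Fa2h* was lower in both treated skins. *Fa2h* was the top gene of the *Scd1*-rich region, which held 4 UVR, 14 retinol-treated and 1 HPR-treated spots. The difference between treatments was not tested, since each had 1 section.

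Collagen transcripts made up less of the whole UVR section than of control skin, with a list median of -1.27. A larger epidermal share of UMIs in UVR skin is a candidate explanation: within the middle region the median was 0.299. Depth per spot stays open beside it: among spots between 311.5 and 1141 UMIs, the control quartiles, the median was 0.305. Those spots were mostly of the middle region, 107 of 169 in control and 130 of 194 in UVR skin, so this test does not separate depth from tissue layer. A change of collagen transcripts within the middle region stays open as well: the lower bound of its interval was 0.0457, but that covers counting error between single sections only, and exchanging upper and lower would turn the sign.

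Stress keratins such as *Krt16* and *Krt6b* were higher in UVR than control skin. A larger epidermal share of spots cannot be the whole cause, because the outer-region median was 2.87 and thus no smaller than over the section. Depth per spot cannot be the whole cause either, since 43 control and 59 UVR outer-region spots within the control quartiles of UMIs gave a median of 2.90 over 8 genes. Probes shared within the *Krt6*, *Sprr* and *Stfa* families cannot be the whole cause. The 7 measured genes outside them (*Krt16*, *Krt17*, *Fabp5*, *Gjb2*, *Gjb6*, *Slpi* and *Tgm3*) had a median of 2.43. These still include related genes, *Krt16* with *Krt17* and *Gjb2* with *Gjb6*. Probe sequences were not examined, so sharing among such relatives stays open. Differences between single mice, and the reading of upper and lower, stay open, so a response to UVR is 1 candidate explanation.

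Both treated skins differed from UVR skin alike, with *Alox8* higher and *Cyp2s1* lower in each. Counting error of the shared UVR section cannot be the whole cause: simulated sections gave a covariance of 0.0115, against 0.385 observed. A difference between capture areas cannot be told apart from treatment. In the outer regions 48 genes were at least 2-fold higher and 152 at least 2-fold lower in both comparisons. Only 61 of them had at least 20 UMIs in the muscle regions in each comparison. These 61 had a median shift of 0.44 in the muscle regions (quartiles -0.12 to 1.26), against 1.41 in the outer regions. Among the 61, the 22 higher genes had a muscle shift of 1.39 and the 39 lower genes 0.12. Keratinocyte RNA in muscle spots differed too, with *Jup* at 1798 CPM in UVR, 5333 CPM in retinol-treated and 7241 CPM in HPR-treated muscle regions. The 61 genes also included the muscle genes *Myh4*, *Mylpf*, *Ckm* and *Tpm2*. Region 0 held 130 of 164 UVR muscle spots, 15 of 131 retinol-treated and 0 of 194 HPR-treated ones. These differences keep this test open.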

How the results depend on the processing

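Alternatives on single regions, on either image side or equal total UMIs of the outer regions, and without both muscle regions were chosen after the results were seen, as was the spot-grid reading of the position counts; all others were set before. The counts of list medians leave out the spot-grid reading, whose turns are given below. Of 1472 alternative values of whole-section list medians, 1304 stayed within the bounds set, 88 were stronger, 70 weaker and 10 reversed. Of 653 in the outer regions, 12 reversed, and of 260 in the middle region, 1. Of 1588 alternative log2 ratios of named genes over the section, again without the spot-grid reading, 387 moved and 9 reversed. No alternative touches the limit of 1 section per group.

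Counting each spot equally gave collagens -0.39 for UVR over control and 0.32 for retinol over UVR. *Eln* turned from -1.04 to 0.30 and *Dhrs3* from -1 to 0.38 for UVR over control. For HPR over UVR, matrix proteases turned from 0.57 to -0.44 and interferon genes from 0.99 to -0.0630. HPR over retinol had 40 higher and 89 lower genes.

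Thinning to equal total UMIs per section left 89 higher and 79 lower genes for UVR over control, 61 and 59 for retinol over UVR, 49 and 70 for HPR over UVR, and 1 and 19 for HPR over retinol. Sebaceous markers turned to 0.0126 for UVR over control and from -0.58 to 0.11 for HPR over retinol. In the same order, genes with at least 20 UMIs gave 760 and 1026, 407 and 858, 378 and 920, and 201 and 241. These genes numbered 5898, 6445, 6373 and 5306. At least 500 UMIs gave 98 and 36, 51 and 71, 30 and 73, and 1 and 10, and raised the correlation of both treatments from 0.81 to 0.86. No minimum with a pseudocount gave 2167 and 3364, 1018 and 1583, 964 and 1623, and 1086 and 1072, with collagens at 0.10 for retinol over UVR.

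Spots with at least 1000 UMIs gave collagens -0.53 for UVR over control and 0.23 for retinol over UVR, 391 genes lower for HPR over UVR and 77 lower for HPR over retinol. The left side of the image gave 175 higher and 97 lower genes for UVR over control, 142 lower and collagens at 0.0033 for retinol over UVR, and 61 higher and 120 lower for HPR over UVR. The right side gave 6 higher and 25 lower genes for HPR over retinol, sebaceous markers at 0.0234 and collagens at -0.0391. Median-of-ratios scaling gave 30 higher genes for HPR over retinol, and totals without the 50 most abundant genes gave 32 higher and 27 lower.

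Weighting the outer, middle and muscle layers alike, without the *Scd1*-rich region, left 88 lower genes for UVR over control. It turned collagens to 0.25, *Col3a1* from -1.95 to 0.19, *Eln* to 0.89 and *Dhrs3* to 0.23. It gave collagens 0.12 for retinol over UVR, matrix proteases -0.35 for HPR over UVR and 30 higher genes for HPR over retinol. Without the regions led by muscle or adipocyte markers (regions 0 and 3), collagens stood at -0.0371 for UVR over control and 0.29 for retinol over UVR. Region 3 is the whole middle region, where fibroblast markers were high, so these collagen values come from the remaining layers. Skeletal muscle markers turned from -1.22 to 2.40 for retinol over UVR and from -1.41 to 2.53 for HPR over UVR. For HPR over UVR, 162 genes were higher, and *Myh4* turned to 0.73, *Pvalb* to 1.04 and *Mlf1* to 2.18. These turns follow from the spots removed: region 0 held 130 UVR, 15 retinol-treated and 0 HPR-treated spots, and region 4 with 34, 116 and 194 stayed in. Without both muscle regions, collagens stood at 0.32 for retinol over UVR, and *Myh4* turned from -1.67 to 0.25 for HPR over retinol.

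Reading upper and lower by the spot grid exchanged the groups on each area. UVR over control then had 191 higher and 312 lower genes, and 0 of 9 lists and 0 of 25 named genes kept their direction. Retinol over UVR had 122 lower genes, and 5 of 10 lists and 10 of 16 genes kept it. HPR over UVR had 214 higher and 145 lower genes, with 5 of 11 lists and 9 of 16 genes. HPR over retinol had 41 higher and 19 lower genes, with 0 of 6 lists and 0 of 10 genes, again fixed by the exchange. Retinol-treated skin was then nearer to control for 140 of 191 higher genes, and HPR-treated skin for 152.

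Within the regions, clustering with the outcome genes placed 150 control spots in a region with *Krt77*, *Krt10* and *Scd1* on top, called *Scd1*-rich. It left 9 control spots in the outer regions. For UVR over control there, stress keratins turned to -0.66, division genes to -2.01, retinoid genes from 0.70 to -1.73, TGF-beta genes from 0.98 to -1.77 and *Tcf23* from 4.53 to -0.0624, and keratinocyte markers in the middle region turned from -0.43 to 0.0774. A resolution of 0.3 gave middle-region collagens of 0.63. Region 2 alone turned UVR-over-control medians of spinous and cornified genes from -0.32 to 0.26, barrier lipid genes from -0.68 to 0.19 and TGF-beta genes to -0.25, lowered division genes to 0.48, and turned collagens from 0.76 to -0.50 for HPR over retinol. Region 1 alone turned retinoid genes to -0.16 and TGF-beta genes to -0.65 for UVR over control. On the right side of the outer regions, HPR over retinol had collagens at -0.0509, basement membrane genes from 0.40 to -0.31 and division genes from 0.02 to -0.82.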

Other observations

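The tests and gene choices in this part were made after the results were seen. Muscle beneath the skin differed between sections in its myosins. The fast myosin *Myh4* supplied 96.2% of *Myh1*, *Myh2*, *Myh4* and *Myh7* UMIs in the control muscle regions (exact 95% interval 95.7% to 96.8%), 84.4% in UVR, 84.9% in retinol-treated and 55.9% in HPR-treated skin (54.0% to 57.9%). *Myh1* supplied 3.69%, 15.1%, 13.7% and 41.5%, and *Myh2* 0.0589%, 0.480%, 1.48% and 2.56%. *Myh7* had no UMI in any of these regions. The control values came from 22 spots, against 164, 131 and 194 in the other sections. The muscle regions differed in make-up: region 0, with *Myh4* on top, and region 4, with *Myh2*, held 12 and 10 control spots, 130 and 34 UVR spots, 15 and 116 retinol-treated spots, and 0 and 194 HPR-treated spots. The myosin shares thus came from unlike mixes of regions 0 and 4. The mix alone does not order the shares: UVR and retinol-treated skin had unlike mixes but *Myh4* shares of 84.4% and 84.9%.

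The IgA heavy chain gene *Igha* was highest in the middle region of UVR skin, at 4315 CPM (3945 to 4710), against 1554 CPM in control, 1023 CPM in retinol-treated and 2869 CPM in HPR-treated skin. Over the whole section *Igha* was highest in control skin, at 745 CPM against 269 CPM in UVR skin, and in the outer regions it stood at 154 against 69.2 CPM. In the middle region the light chain gene *Igkc* followed the same order between UVR (425 CPM) and retinol-treated skin (86.0 CPM) on fewer UMIs, 49 and 9. It did not share the order of control (238 CPM) and HPR-treated skin (149 CPM), on 23 and 19 UMIs. *H2-Ab1*, a class II antigen-presentation gene, stood at 249 CPM in the outer regions of control skin, 52.7 CPM in UVR, 287 CPM in retinol-treated and 229 CPM in HPR-treated skin. *Cd74* stood at 503, 36.7, 132 and 190 CPM there. The pigment gene *Tyrp1* had no UMI in the outer regions of control skin, with an exact 95% upper bound of 21.8 CPM, and stood at 63.1, 33.1 and 98.6 CPM in the others. In the middle region it stood at 124 CPM in control, on 12 UMIs, 104 CPM in UVR, 210 CPM in retinol-treated and 196 CPM in HPR-treated skin. Over the section control skin had 36.8 CPM (19.0 to 64.3) and UVR skin 57.8 CPM.

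The junction gene *Jup* took 5.51% of all UMIs in control skin, 6.34% in UVR, 6.79% in retinol-treated and 8.95% in HPR-treated skin, so that a single gene weighed on the totals. The lipid-rich region with *Scd1* held 9.44% of control spots (6.55% to 13.1%), 0.618% of UVR spots, 2.57% of retinol-treated spots and 0.155% of HPR-treated spots. The region led by *Myh4* and *Pvalb* held 20.1% of UVR spots and 0 of 644 HPR-treated spots, with an exact 95% upper bound of 0.571%.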
